A study of Mus musculus with 8 samples.

How the data were processed

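Bulk RNA sequencing of gastrocnemius, a calf muscle made mostly of fast fibres, was available for 8 mice in 2 groups. Per the labels and the series' design text, male C57BL/6J mice aged 12 weeks were given pooled serum from K/BxN mice, a strain that develops antibody-driven arthritis, as 100 µL injections into the peritoneum on day 0 and day 2. Serum of this kind passes the arthritis to the recipient. The RA group (n = 4 mice) had serum alone. The RA+Dipy group (n = 4 mice) also had dipyridamole at 25 mg/kg each day from day 0. Muscle was taken on day 16. Dipyridamole blocks equilibrative nucleoside transport, which raises adenosine outside cells, and inhibits several phosphodiesterases. Samples were grouped by their titles. The labels are not uniform: the genotype field reads K/BxN for mice that the design text describes as serum recipients, and the treatment field names dipyridamole for all 8 samples, including the RA group. The labels name poly(A) libraries from the TruSeq system, whereas the design text names a directional NEBNext kit with 500 ng of RNA. No muscle from mice without arthritis was analysed here, and the vehicle given to the RA group is not given in the sources used here.

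The authors deposited, for each library, raw read counts per protein-coding gene (gene symbol and count, not normalized). Per the submitters' processing notes and the design text, single reads of 100 nt were trimmed with fastp 0.20.0, aligned to mouse GRCm38.p6 with STAR 2.7.3a and counted with HTSeq in its non-stranded mode. The submitters then used DESeq2 1.44.0 and GSEA 4.3.3; the output of those steps was not used here. The annotation release is not given in the sources used here. Each table held 21859 lines with no line for unassigned reads, so a library total here is a sum over protein-coding genes. A total of 24 symbols stood on more than 1 line; their counts were summed, which left 21833 symbols. Counting without strand cannot tell the reads of a gene from those of a partner on the opposite strand where their exons overlap. Apart from strand, reads are hard to assign between near-identical copies, such as Hba-a1 and Hba-a2 or the processed copies of ribosomal protein genes. In the GENCODE vM21 annotation of GRCm38, 35 of the 110 genes chosen for naming share exon bases with another gene, 28 of them with one on the opposite strand. Totals ran from 16.4 to 50.6 M (mega) counts per library. A count of 0 (upper limit of 3 counts) allows 0.0592 CPM in the deepest library and 0.183 CPM in the shallowest. These limits cover counting error only, since the reads carry no molecular identifiers.

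Genes were kept by the edgeR function filterByExpr with a minimum count of 10, which left 12755 genes and removed 9078. Library sizes were scaled by TMM. The groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates and the group as the sole term, on the counts as deposited. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and all tests were two-sided. Fold changes are given as log2 of RA+Dipy over RA with their standard error (SE), and levels as CPM (counts scaled to a common library size, with TMM factors), mean ± SD over the libraries of a group. Each library came from a separate mouse according to the group sizes in the design text. No pair of libraries within a group agreed within sampling noise: the smallest chi-square per degree of freedom between a pair was 29.3.

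A total of 42 gene lists (836 genes, 832 of them in the tables) covering muscle breakdown, metabolism, signalling, inflammation and markers of the other cell types that a piece of muscle can hold were written before the data were examined, as were the tests, the alternatives and the rule for naming genes. The 41 lists with at least 3 tested members were tested with camera (limma 3.58.1), which asks whether a list's genes rank apart from all other genes, with a preset correlation between genes of 0.01. Beside it, camera was run with the correlation estimated from the data, and fry was run as a test of whether a list's genes move one way on balance. The B cell marker list had 0 tested members. The rule for naming genes took up to 12 genes per direction past the threshold or, where fewer than 5 passed, the 6 with the smallest p in that direction, given as values. It also took up to 3 members with the smallest p of each list passing camera, up to 2 of each other list, and 22 genes fixed by name. This gave 110 genes with a fold change, not all of which are described. Gene positions come from GENCODE vM21 (GRCm38).

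Other settings fixed in advance were DESeq2 size factors and upper-quartile factors in edgeR, no low-count filter, a mean of at least 1 CPM, the replicate number as a block, the DESeq2 1.42.0 Wald test, limma-voom with and without library weights. They also included fits without robust estimates or without the 24 genes that took over 1% of any library, and leaving out each library in turn. Chosen after seeing the data were the fit without 2 libraries that stood apart from the rest, per-library offsets for GC content and transcript length (splines with 5 degrees of freedom; 98.9% of tested genes had both values) and an exact permutation test of list scores over the 70 assignments of the 8 libraries, whose smallest two-sided p is 0.0286. A list score is the mean log2 CPM of its members in a library, with a prior count of 2.

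The test was tried on simulated counts drawn from the means, dispersions and library sizes of the real data, with 200 genes changed. With all 8 libraries, 6 of 100 genes changed 2-fold and 75 of 100 changed 4-fold were recovered, with 4 false calls among 85 calls. With the 6 libraries that lay close together, 81 and 99 of 100 were recovered, with 13 false among 193 calls. The changed genes were drawn from better-counted genes only, so recovery at low counts was not tried. The simulated noise was independent between genes and had the same dispersion in every library. The real libraries differ from this, so the simulated rates of false calls do not carry over to them.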

Results

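Gene expression was compared in gastrocnemius muscle of mice with serum-transfer arthritis that were given dipyridamole (RA+Dipy, n = 4) or not (RA, n = 4). The series presents dipyridamole as a preventive treatment for rheumatoid cachexia, the loss of muscle that accompanies arthritis. The comparison asks which muscle transcripts differ when the drug is given from the day of the first serum injection. The RA libraries held 50.6, 24.8, 25.7 and 16.7 M (mega) counts in replicates 1 to 4. The RA+Dipy libraries held 16.4, 25.4, 24.1 and 21.4 M. All 8 libraries had the profile of fast muscle. Myh4, the fast myosin heavy chain, took 2.11% to 6.06% of counts, Acta1, skeletal actin, 1.76% to 4.40%, and Pvalb, the calcium buffer parvalbumin, 1.32% to 4.56%.

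One library in each group stood apart from the other 6. RA replicate 4 and RA+Dipy replicate 1 deviated from the 8-library median of each gene with a spread of 1.24 and 0.75 log2 units over 3366 well expressed genes, against 0.13 to 0.28 in the other 6 libraries. In these libraries 42.6% and 21.5% of the genes lay more than 2-fold from the median, against 0.0594% to 1.07% in the others. Atp2a1, the calcium pump of fast fibres, took 0.582% of counts in RA replicate 4 and 0.196% in RA+Dipy replicate 1, against 1.77% to 2.57% elsewhere. Pvalb was highest in the same libraries, at 4.56% and 4.31%. Other traits set the 2 libraries apart from each other. The mitochondrially encoded mt-Co1 took 3.31% of counts in RA replicate 4 and 0.533% in RA+Dipy replicate 1, against 1.02% to 2.20% elsewhere. Genes of the lowest GC content had a median deviation of −0.63 log2 units in RA replicate 4 and 0.30 in RA+Dipy replicate 1. The median Spearman correlation with the other libraries was 0.872 and 0.930, against 0.972 to 0.986. The common biological coefficient of variation was 0.386 with all 8 libraries and 0.183 without these 2. Of the 110 genes chosen for naming, the log2 fold change of 54 moved by over 1.5 times or changed sign without RA replicate 4 (52 of them to a smaller value or the other sign), and that of 23 without RA+Dipy replicate 1.

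**Figure D1:**
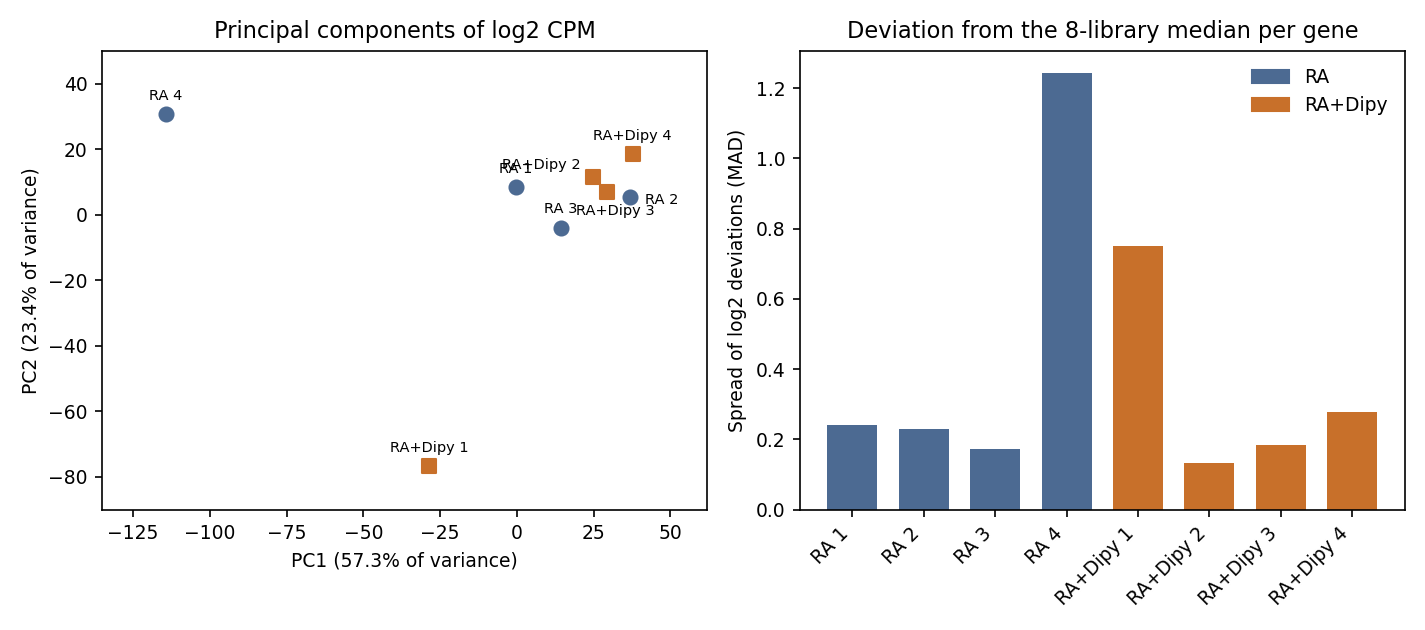
Left, the first principal components of log2 CPM over all tested genes, with 1 point per library (RA as circles, RA+Dipy as squares). Right, bars give each library's spread of log2 deviations from the 8-library median of each gene, as the scaled median absolute deviation (MAD) over 3366 genes; RA replicate 4 and RA+Dipy replicate 1 stand at 1.24 and 0.75, and the other 6 between 0.13 and 0.28.

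No single gene passed the adjusted threshold between RA+Dipy and RA muscle, while as groups the genes of extracellular matrix, macrophages and the interferon response rose with dipyridamole and those of Schwann cells fell, by camera with its preset correlation. With an estimated correlation 0 of 41 lists passed (smallest adjusted p = 0.667), and by fry 0 (0.675). The genes with the smallest p among those higher in RA+Dipy were Ctss, the lysosomal protease cathepsin S of antigen-presenting cells, at 7.82 ± 1.89 CPM in RA and 21.2 ± 7.26 in RA+Dipy (SD, n = 4 each; log2 fold change 1.44, SE 0.32). Next came the interferon-induced Ifit2 at 2.03 ± 0.589 and 5.02 ± 1.25 CPM (1.30, SE 0.30), and the matrix protein periostin, Postn, at 10.4 ± 3.81 and 37.2 ± 17.4 CPM (1.83, SE 0.44). Evi2a (log2 1.18), the interferon-induced GTPase Gbp3 (0.98) and the potassium channel Kcnj15 (2.29, at 0.138 and 0.738 CPM) followed. On the lower side stood Grem1, a secreted antagonist of bone morphogenetic proteins, at 1.59 ± 0.660 and 0.535 ± 0.0418 CPM (log2 fold change −1.54, SE 0.39). The same side held the death-domain receptor Tnfrsf25 (−1.63, SE 0.41), Xrra1 (−1.76), Krtcap3 (−1.54), Socs1, a feedback inhibitor of cytokine signalling (−1.38, SE 0.41), and Doc2g (−1.69). For these 12 genes except Socs1 and Doc2g, the values of the 2 groups did not overlap. Krtcap3 stood at −1.01 without RA replicate 4.

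In numbers, 0 of 12755 genes were higher and 0 lower at an adjusted p under 0.05 in edgeR, and the smallest adjusted p was 0.882. At an unadjusted p under 0.05 there were 488 genes, 214 higher and 274 lower, where chance alone gives about 638. The groups did not overlap for 186 genes that were higher and 161 that were lower, 2.72% of genes, and chance gives 2.86%. DESeq2 called 0 genes (815 at an unadjusted p under 0.05; smallest adjusted p 0.446) and limma-voom 0 (379). Of 20 alternatives run, the sole one with calls was limma-voom with library weights, which called 111 genes higher and 22 lower (3638 at an unadjusted p under 0.05). It gave RA replicate 4 a weight of 0.110 and RA+Dipy replicate 1 a weight of 0.174, against 4.80 for RA+Dipy replicate 3. Without the 2 libraries that stood apart, edgeR called 0 genes, with 1461 at an unadjusted p under 0.05. That count was 296 without RA replicate 1, 1187 without RA replicate 2, 184 without RA+Dipy replicate 3 and 178 without RA+Dipy replicate 4. Ctss lies on chromosome 3 at 95526786 to 95556403, Ifit2 on chromosome 19 at 34550694 to 34576419, Postn on chromosome 3 at 54361109 to 54391037, and Grem1 on chromosome 2 at 113746164 to 113758646 (GRCm38). None of these 4 shares exon bases with another annotated gene.

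**Figure D2:**
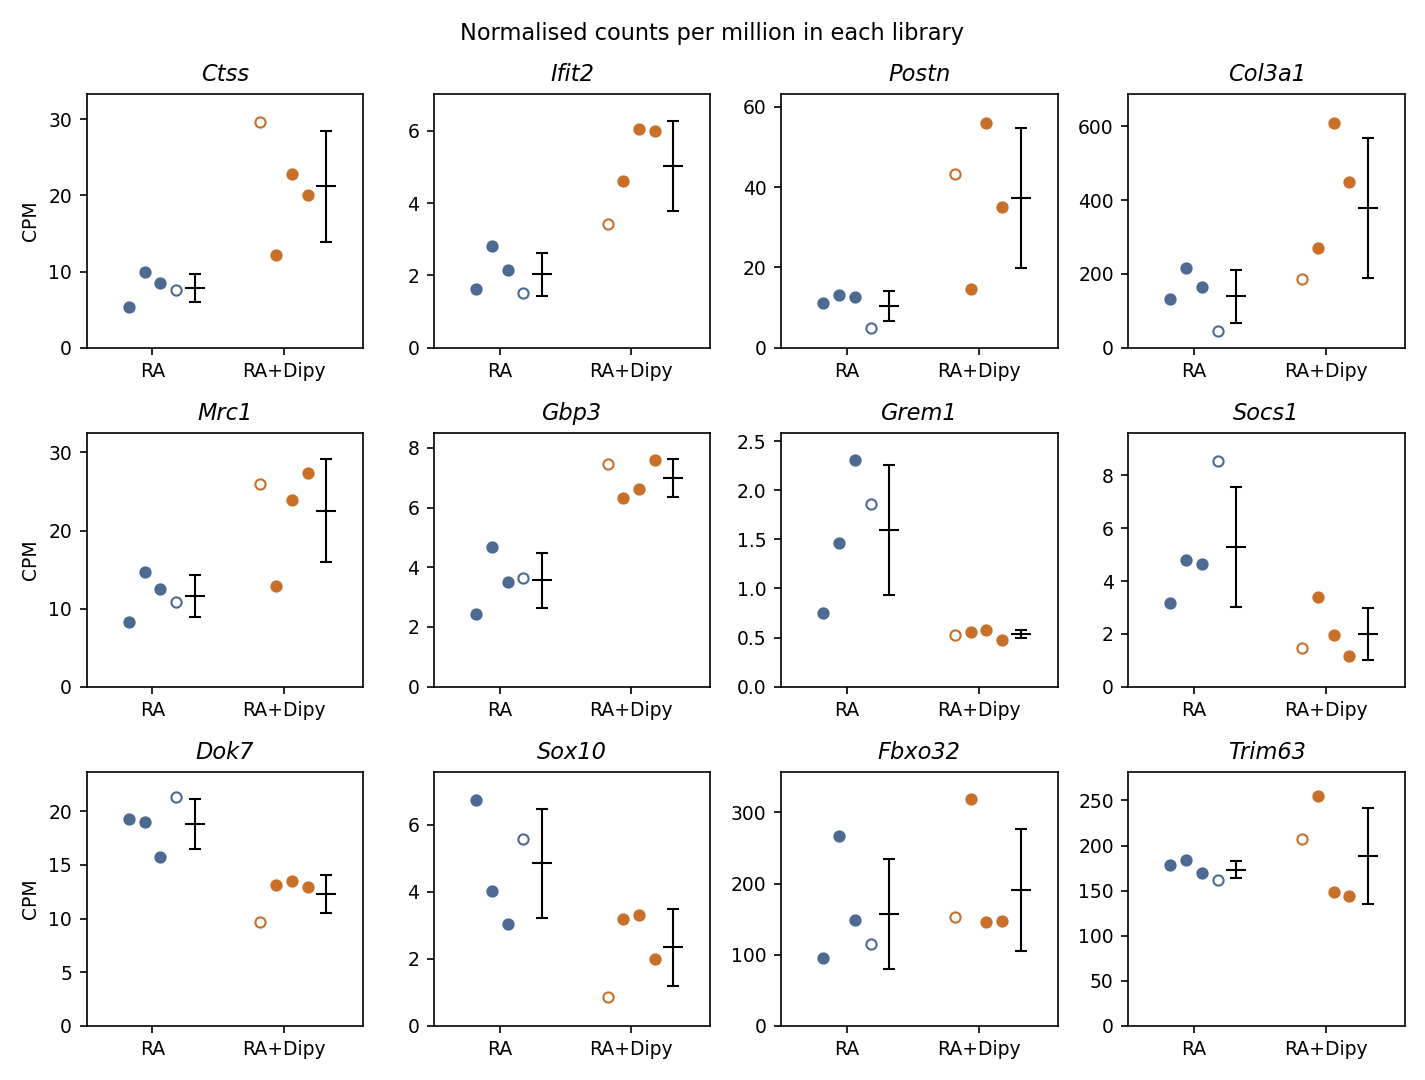
CPM (linear axis from 0) of 12 named genes in each library, with filled points for 6 libraries, open points for RA replicate 4 and RA+Dipy replicate 1, and a bar for the mean ± SD of the 4 libraries of a group. None of the 12 passed the adjusted threshold in edgeR; Ctss averaged 7.82 CPM in RA and 21.2 in RA+Dipy, and the atrophy ligase Trim63 173 and 189.

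Genes of the extracellular matrix rose as a list: 25 of 34 were higher in RA+Dipy, with a median log2 fold change of 0.54 (camera adjusted p = 3.70e-08; adjusted p = 0.667 with an estimated correlation). Besides Postn, fibrillar collagen III, Col3a1, stood at 139 ± 71.1 CPM in RA and 378 ± 189 in RA+Dipy (log2 1.44, SE 0.51), and the proteoglycan lumican, Lum, at 17.8 ± 5.06 and 38.3 ± 10.8 (1.10, SE 0.31). Adjusted over the list alone 0 genes passed, as over all genes, and 9 had an unadjusted p under 0.05. The list score was 5.51 ± 0.15 in RA and 6.00 ± 0.31 in RA+Dipy (log2 CPM, SD), with an exact permutation p of 0.0286, the smallest that the 70 assignments allow, and 0.781 after adjustment over 41 lists. The median was 0.57 without the 2 libraries that stood apart, and the list passed camera under each of 18 alternatives that kept the preset correlation (adjusted p 3.92e-16 to 0.000213).

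Macrophage markers rose as well: 12 of 14 were higher, with a median of 0.70 (camera adjusted p = 1.17e-06; adjusted p = 0.667 with an estimated correlation). The pore-forming Mpeg1 stood at 4.01 ± 1.71 CPM in RA and 10.4 ± 4.29 in RA+Dipy (log2 1.37, SE 0.40), the mannose receptor Mrc1 at 11.6 ± 2.67 and 22.5 ± 6.58 (0.96, SE 0.30) and lysozyme, Lyz2, at 58.6 ± 15.9 and 113 ± 41.9 (0.95, SE 0.34). Of the 14 markers 0 passed when adjusted over the list alone, as over all genes, and 5 had an unadjusted p under 0.05. The call held under each of the 18 alternatives with the preset correlation (adjusted p 3.05e-15 to 0.000590), and the exact permutation p of the score was 0.0571. The scores of the groups overlapped: RA+Dipy replicate 2 (2.78) lay near RA replicate 2 (2.75) and below RA replicate 4 (3.38). Of the complement list, 11 of 16 members were higher (median 0.35, camera adjusted p = 0.0484; adjusted p = 0.845 with an estimated correlation), and 3 of its members, C1qa, C1qb and C1qc, are also on the macrophage list. C3ar1, the receptor for complement fragment C3a, had a log2 fold change of 0.90 (SE 0.34), C1s1 of 0.57 (SE 0.27) and Cd55 of 0.55 (SE 0.38). Of its members 0 passed when adjusted over the list alone, as over all genes. The complement call was lost with DESeq2 size factors (0.0513) and upper-quartile factors (0.0567) and without RA replicate 1 (0.241), 2 (0.244) or 3 (0.132) or RA+Dipy replicate 1 (0.111), 3 (0.113) or 4 (0.408), in a range from 8.49e-06 to 0.408. Its median was 0.32 with DESeq2 size factors and 0.42 with upper-quartile factors or without RA+Dipy replicate 1. It was 0.20, 0.23 and 0.22 without RA replicates 1, 2 and 3, and 0.27 and 0.16 without RA+Dipy replicates 3 and 4. Cd55 stood at 0.31 without RA replicate 4 and at 0.36 without RA+Dipy replicate 1.

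Interferon-response genes rose by camera, with 20 of 30 higher and a median of 0.21 (adjusted p = 0.000713; adjusted p = 0.667 with an estimated correlation). Gbp3 stood at 3.56 ± 0.917 CPM in RA and 7 ± 0.627 in RA+Dipy (log2 0.98, SE 0.26) and Parp14 at 6.00 ± 2.02 and 10.6 ± 1.69 (0.82, SE 0.28). Ifit2 and Gbp3, 2 genes, passed when adjusted over the list alone, against 0 over all genes. The call held under each of the 18 alternatives with the preset correlation (adjusted p 4.58e-13 to 0.0288), although the size varied: the median was 0.52 without RA replicate 4, 0.08 without RA replicate 1, 0.07 without RA replicate 3 and 0.12 without RA+Dipy replicate 4. Without both libraries that stood apart it was 0.43. The exact permutation p of the score was 0.143. RA replicate 4 had the highest score of all 8 libraries (2.85, RA+Dipy 2.57 to 2.78), so the scores of the groups overlapped.

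Adipocyte markers had 9 of 13 members higher, with a median of 0.69 (camera adjusted p = 0.0484; adjusted p = 0.886 with an estimated correlation). The fat-cell hormone adiponectin, Adipoq, stood at 15.3 ± 6.15 CPM in RA and 41.0 ± 40.0 in RA+Dipy (log2 1.43, SE 0.57), Pck1 had a log2 fold change of 2.04 (SE 0.82) and leptin, Lep, of 1.69 (SE 0.73). A single library decided the direction: Adipoq was at 101 CPM in RA+Dipy replicate 4 and at 19.9 to 22.9 CPM in the other 3, and without that library the list's median was −0.41 (adjusted p = 0.647, in a range from 3.46e-06 to 0.647). Adipoq then stood at 0.47, Pck1 at 0.21 and Lep at 0.53. The call was also lost without RA replicate 1 (0.0713), 2 (0.536) or 3 (0.346), and the median was 1.44 without RA replicate 4. It was lost with DESeq2 size factors (0.0513), upper-quartile factors (0.0633) and limma-voom values (0.0753). Adjusted over the list alone 0 passed, as over all genes.

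Schwann cell and nerve markers fell as a list: 10 of 11 were lower, with a median of −0.55 (camera adjusted p = 0.00115; adjusted p = 0.667 with an estimated correlation). The myelin genes Prx, at 30.0 ± 12.7 CPM in RA and 16.2 ± 5.06 in RA+Dipy (log2 −0.88, SE 0.35), and Mbp, at 101 ± 62.5 and 51.1 ± 11.8 (−0.98, SE 0.41), and the glial transcription factor Sox10, at 4.85 ± 1.64 and 2.34 ± 1.15 (−1.04, SE 0.42), had the smallest p. None of the 11 passed when adjusted over the list alone or over all genes, and 4 had an unadjusted p under 0.05. The list passed under each of the 18 alternatives with the preset correlation (adjusted p 9.47e-05 to 0.0132), and its median was −0.50 without the 2 libraries that stood apart. Mbp stood at −0.45 without RA replicate 4 and at −0.51 without both libraries, and Prx at −0.50 without both. The exact permutation p of its score was 0.114. The scores of the groups overlapped: RA replicate 3 (2.95) lay below RA+Dipy replicates 1 (3.10) and 3 (3.12). RA replicate 4 had the highest score (4.07).

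Genes of calcium handling and excitation-contraction coupling fell by camera, with 17 of 19 lower and a median of −0.31 (adjusted p = 0.00242; adjusted p = 0.764 with an estimated correlation). Members with the smallest p were the calcium channel subunits Cacng1, at 639 ± 498 CPM in RA and 287 ± 61.8 in RA+Dipy (log2 −1.16, SE 0.48), and Cacnb1 (−0.91, SE 0.41), and the calcium store protein calsequestrin, Casq1 (−0.84, SE 0.45). The denervation and neuromuscular junction list fell as well, with 14 of 16 lower and a median of −0.42 (adjusted p = 0.00712; adjusted p = 0.764 with an estimated correlation). Its leading members were Dok7, which activates the junction kinase MuSK, at 18.9 ± 2.33 and 12.3 ± 1.80 CPM (−0.61, SE 0.22), the receptor-clustering Rapsn (−0.78, SE 0.32) and myogenin, Myog, which is induced by denervation (−0.81, SE 0.39). No gene of either list passed when adjusted over the list alone or over all genes. Both calls were lost without the 2 libraries that stood apart, with medians of −0.14 and −0.05 (adjusted p = 0.181 and 0.567, the highest of their 18 alternatives, where the lowest were 0.000660 and 0.000601). The calcium call was lost without RA+Dipy replicate 1 alone (0.0533; median −0.51). The junction call was lost without RA replicate 4 (0.200; median −0.12) and without RA+Dipy replicate 1 (0.0736; median −0.41). Without RA replicate 4 the named genes were closer to 0, with Cacng1 at −0.45, Cacnb1 at −0.34, Casq1 at −0.26, Rapsn at −0.38 and Myog at −0.39. The calcium median was then −0.10 (adjusted p = 0.0379), and without RA replicate 3 the junction median was −0.64.

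Slow-fibre sarcomere genes had 10 of 11 members lower, with a median of −0.40 (camera adjusted p = 0.0484; adjusted p = 0.845 with an estimated correlation): Myl6b had a log2 fold change of −1.10 (SE 0.44), Myl2 of −0.58 (SE 0.47) and Tnnt1 of −0.61 (SE 0.50). The call was lost with DESeq2 size factors (0.0513) and without RA replicate 1 (0.0612), RA replicate 3 (0.508) or RA+Dipy replicate 4 (0.647), in a range from 0.00394 to 0.647. The median was −0.61 without RA replicate 2, −0.24 without RA replicate 3, −0.22 without RA replicate 4, −0.69 without RA+Dipy replicate 1 and −0.20 without RA+Dipy replicate 4. Myl6b stood at −0.54 without RA replicate 4, and Myl2 and Tnnt1 at −0.29 and −0.31 without RA+Dipy replicate 4. Cytosolic ribosomal protein genes had 32 of 59 lower, with a median of −0.14 (camera adjusted p = 0.0484; adjusted p = 0.917 with an estimated correlation), and 0 with an unadjusted p under 0.05. Rpl29 (−0.67), Rpl28 (−0.76) and Rps10 (−0.96, at 0.782 and 0.383 CPM) had the smallest p, and stood at −0.33, −0.30 and −0.46 without RA replicate 4. Their call was lost with DESeq2 size factors (0.0513), at a mean of at least 1 CPM (0.0569) and with GC and length offsets (0.112). It was also lost without RA replicate 1 (0.130), 3 (0.132) or 4 (0.324; median 0.12) or RA+Dipy replicate 2 (0.445; median 0.00148), 3 (0.428; median 0.02) or 4 (0.959; median 0.07). Without RA replicate 2 the median was −0.28, without RA+Dipy replicate 1 it was −0.67, and without both libraries that stood apart −0.46 (adjusted p = 1.28e-22, the lowest of the range, which reached 0.959). Adjusted over the list alone 0 genes of either list passed, as over all genes.

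Camera with the preset correlation thus called 10 of 41 lists, 5 higher and 5 lower, and 6 without RA replicate 1 or with DESeq2 size factors. With GC and length offsets it called 13. With an estimated correlation it called 0 (smallest adjusted p 0.667), and fry called 0 (0.675). Among the 10 lists the estimate ran from 0.11 (interferon response) to 0.75 (adipocyte markers), above the preset 0.01. Alternatives that keep the preset value therefore do not check it. The exact permutation test of scores gave 1 list with an unadjusted p under 0.05 and 0 after adjustment (smallest 0.781). Without the 2 libraries that stood apart, 12 lists passed with the preset correlation, 8 of them among the 10 above in the same direction, and 0 with an estimated correlation (smallest adjusted p 0.398).

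**Figure D3:**
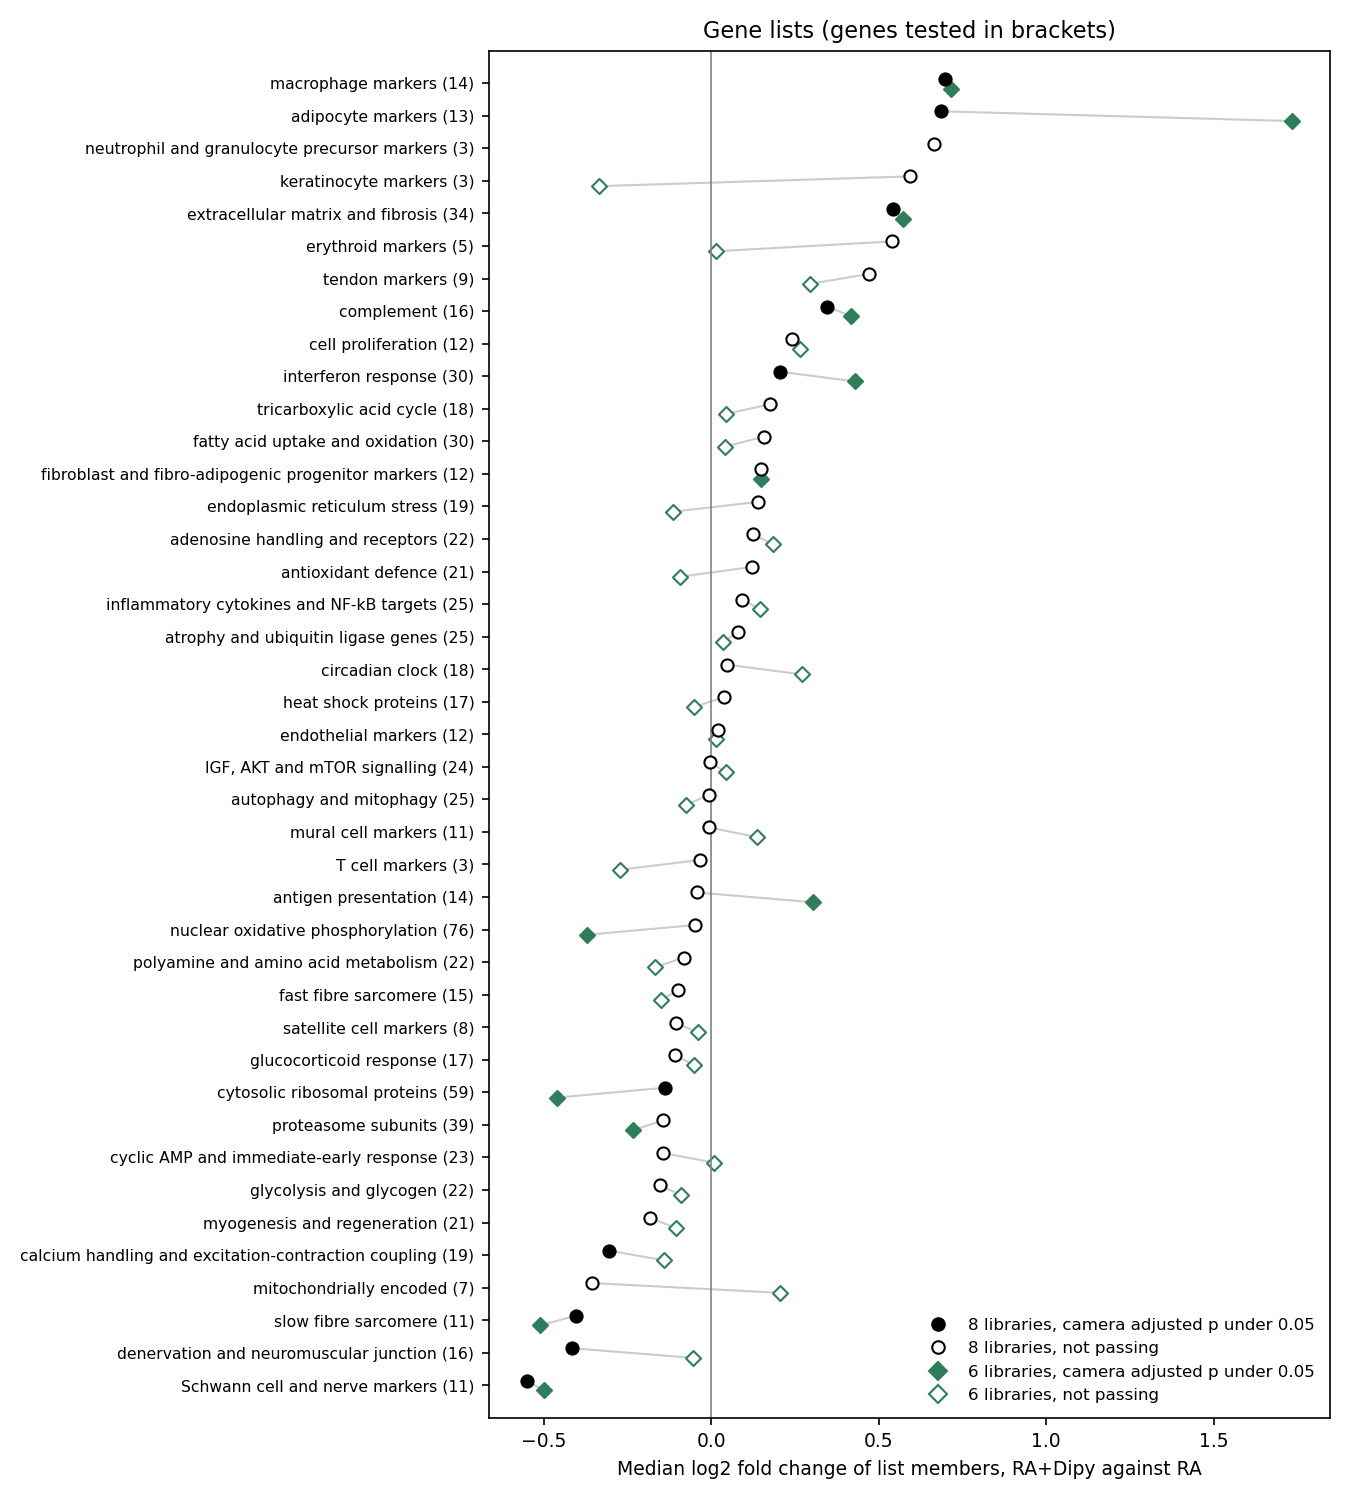
Median log2 fold change (RA+Dipy against RA) of the members of each of 41 gene lists, with the number of genes tested in brackets. Circles show all 8 libraries, diamonds the 6 libraries without RA replicate 4 and RA+Dipy replicate 1 (40 lists), and filled symbols a camera adjusted p under 0.05 with the preset correlation; 10 circles and 12 diamonds are filled.

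Muscle breakdown genes, the transcripts most directly tied to cachexia, gave no call between the groups. The list of atrophy and ubiquitin ligase genes had 14 of 25 members higher and a median of 0.08 (mean −0.06; camera adjusted p = 0.994). The atrophy ligases Fbxo32 (atrogin-1) stood at 157 ± 77.2 CPM in RA and 191 ± 85.5 in RA+Dipy (log2 0.29, SE 0.40) and Trim63 (MuRF1) at 173 ± 9.52 and 189 ± 53.1 (0.12, SE 0.26). Intervals of 2 SE around these folds ran from 0.699 to 2.13 and from 0.755 to 1.57. With 1 library left out Fbxo32 ran from −0.08 (without RA+Dipy replicate 2) to 0.68 (without RA replicate 2), and Trim63 from −0.06 (without RA+Dipy replicate 2) to 0.23 (without RA+Dipy replicate 4). Myostatin, Mstn, which limits muscle mass, had a log2 fold change of −0.06 (SE 0.37), and the transcription factors Foxo1 and Foxo3 of −0.19 (SE 0.36) and −0.07 (SE 0.24). These 3 changed sign with single libraries left out: Mstn stood at 0.35 without RA replicate 2, and Foxo1 at 0.13 and Foxo3 at 0.08 without RA replicate 4. Cdkn1a, the cell-cycle inhibitor p21, was at 36.3 ± 15.6 and 19.5 ± 0.788 CPM without overlap between the groups (−0.90, SE 0.31), and Fbxo31 was at −0.59 (SE 0.28). Neither autophagy and mitophagy genes (25 tested, median −0.01, adjusted p = 0.961; Map1lc3a −1.06, Atg12 0.69) nor proteasome subunits (39 tested, median −0.14, adjusted p = 0.547; Psmd2 −0.86, Psmc5 −0.45) passed, although the proteasome list passed as lower without RA+Dipy replicate 1 (adjusted p = 0.00126, in a range from 4.04e-08 to 0.940). Psmd2 stood at −0.06, Psmc5 at −0.24 and Map1lc3a at −0.25 without RA replicate 4. Without both libraries that stood apart Atg12 stood at 0.26 and Fbxo31 at −0.25. With 1 library left out, the proteasome median ran from −0.25 (without RA+Dipy replicate 1) to 0.06 (without RA replicate 4), the atrophy median from −0.04 (without RA+Dipy replicate 2) to 0.15 (without RA replicate 2) and the autophagy median from −0.06 to 0.04 (without RA replicate 4 and RA+Dipy replicate 1). No member of the 3 lists passed adjusted over the list alone or over all genes. The IGF, AKT and mTOR list was centred on 0 (24 tested, median −0.00375, adjusted p = 0.994), with Igf1 at −0.06 (SE 0.44), Rps6kb1 at 0.46 and Igf1r at −0.41; without RA replicate 4, Igf1 was at 0.50, Rps6kb1 at 0.27 and Igf1r at 0.05, and without RA+Dipy replicate 1 at −0.47, 0.25 and −0.65.

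For genes of muscle identity and repair, the myogenesis and regeneration list had a median of −0.18 (21 tested, adjusted p = 0.362; Megf10 0.80), satellite cell markers −0.11 (8 tested, adjusted p = 0.820; Cdh15 −0.42) and fast-fibre sarcomere genes −0.10 (15 tested, adjusted p = 0.452; Actn3 −0.66). Pax7, the satellite cell transcription factor, had a log2 fold change of −0.11 (SE 0.34) and the myogenic factor Myod1 of −0.31 (SE 0.24). Pax7 stood at 0.14 without RA replicate 1 and at 0.07 without RA+Dipy replicate 1. In energy metabolism, fatty acid uptake and oxidation had 21 of 30 members higher and a median of 0.16 (adjusted p = 0.0526), with Ucp3 at 43.3 ± 20.8 and 86.8 ± 31.6 CPM (log2 1.00, SE 0.41) and Acsl1 at 136 ± 73.0 and 291 ± 57.3 without overlap (1.10, SE 0.46). Pdk4, the kinase that shuts off glucose oxidation, stood at 184 ± 121 and 370 ± 89.6 CPM (1.00, SE 0.48) and Ppargc1a at 22.2 ± 2.31 and 24 ± 4.13 (0.11, SE 0.22). The tricarboxylic acid cycle list had a median of 0.18 (adjusted p = 0.162; Dld 0.83, Sucla2 0.38) and glycolysis and glycogen of −0.15 (0.320; Pgm2 0.55, Pygm −0.63). Nuclear oxidative phosphorylation had one of −0.05 (0.350; Cox6a2 −1.08, Ndufa11 −0.95) and mitochondrially encoded genes of −0.36 (0.452; mt-Nd1 −0.41, mt-Nd4 −0.40). The last median was 0.21 without the 2 libraries that stood apart and 0.17 without RA replicate 4. Oxidative phosphorylation had a median of 0.18 without RA replicate 4 and of −0.53 without RA+Dipy replicate 1, and the tricarboxylic acid cycle of 0.01 without RA replicate 4 and 0.34 without RA replicate 3. The fast-fibre median ran from −0.37 (without RA+Dipy replicate 1) to 0.05 (without RA replicate 1), the satellite cell median from −0.17 (without RA replicate 4) to 0.01 (without RA replicate 3), and the myogenesis median was −0.30 without RA replicate 3. Glycolysis stood at −0.28 without RA+Dipy replicate 3 and fatty acid oxidation at 0.10 without RA replicate 4. Without RA replicate 4, Ndufa11 stood at −0.09, Cox6a2 at −0.41, Pygm and Actn3 at −0.37, Cdh15 at −0.22, Myod1 at −0.14, Dld at 0.54, mt-Nd1 at 0.12 and mt-Nd4 at 0.05. Without RA+Dipy replicate 1, Dld stood at 0.45, Sucla2 at 0.07, Pygm at −0.40, mt-Nd4 at −0.24, Megf10 at 0.50 and Ppargc1a at −0.02. Fatty acid oxidation passed at a mean of at least 1 CPM (0.0459), on limma-voom values (0.0481) and with GC and length offsets (0.00656), in a range to 0.259. It also passed without RA replicate 3 (0.0102) or RA+Dipy replicate 4 (0.0340). So did the tricarboxylic acid cycle without RA replicate 3 (0.0307; range to 0.934) and oxidative phosphorylation, as lower, without RA replicate 2 (0.00856) or RA+Dipy replicate 1 (5.74e-10; range 6.49e-12 to 0.969). With an estimated correlation and all 8 libraries, camera gave an adjusted p of 0.845 for fatty acid oxidation, 0.888 for the tricarboxylic acid cycle and 0.978 for oxidative phosphorylation. The fatty acid median was 0.04 without the 2 libraries that stood apart (adjusted p = 0.226 with the preset correlation). No gene of these 8 lists passed, adjusted over the list alone or over all genes.

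The drug's own targets gave no call. The list of adenosine handling, adenosine receptors and dipyridamole-related phosphodiesterases had 13 of 22 tested members higher and a median of 0.12 (adjusted p = 0.602), which was −0.01 with GC and length offsets. The A2B receptor Adora2b stood at 0.560 ± 0.212 CPM in RA and 1.19 ± 0.543 in RA+Dipy without overlap (log2 1.00, SE 0.42), and Slc29a1, the nucleoside transporter that dipyridamole blocks, at 35.4 ± 8.18 and 25.4 ± 2.86 (−0.48, SE 0.24). The ectonucleotidase Nt5e was at 0.82 (SE 0.46), Adora1 at −0.59 (SE 0.81), Adora2a at −0.33 (SE 0.33) and Pde5a at −0.11 (SE 0.32). Adora3 had 1 to 7 counts per library and was not tested. Cyclic AMP and immediate-early genes, which respond to the second messenger downstream of adenosine receptors, had a median of −0.14 (23 tested, adjusted p = 0.609; Btg2 −0.78, Ier3 −0.79), and 0.01 without the 2 libraries that stood apart. The cyclic AMP median was 0.05 and the adenosine median 0.18 without RA replicate 4. With 1 library left out, the adenosine median ran from 0.02 (without RA replicate 3) to 0.21 (without RA replicate 2). With no low-count filter the adenosine median was −0.0992. Btg2 stood at −0.25, Ier3 at −0.14, Slc29a1 at −0.31, Adora1 at 0.40, Adora2a at −0.20 and Pde5a at 0.24 without RA replicate 4. Without RA+Dipy replicate 1, Adora2b stood at 0.67, Adora1 at −0.32 and Adora2a at −0.21, and Nt5e at 0.43 without both. Adjusted over the list alone 0 genes of either list passed, as over all genes.

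Inflammatory cytokines and NF-kB targets had 14 of 25 members higher and a median of 0.09 (mean −0.01; adjusted p = 0.812). The neutrophil-attracting chemokine Cxcl5 stood at 1.44 ± 0.715 and 0.495 ± 0.257 CPM (log2 −1.55, SE 0.49), the adhesion molecule Vcam1 at 3.74 ± 0.304 and 5.37 ± 1.37 without overlap (0.52, SE 0.25) and Socs3 at 5.50 ± 2.79 and 6.17 ± 2.60 (0.15, SE 0.44). Il6 (0 to 3 counts per library), Tnf (0 to 9) and Il1b (0 to 6) lay below the filter, and a difference in them was not detectable at these counts. Antigen presentation had a median of −0.04 (14 tested, adjusted p = 0.994; H2-Eb1 0.45, Tap2 −0.66) that was 0.31 without the 2 libraries that stood apart and 0.34 without RA replicate 4 (adjusted p = 0.00103, in a range from 0.000566 to 0.997). Without that library the proliferation list passed (0.0205; range to 0.990) and Mt1 stood at 0.37. Glucocorticoid-response genes had a median of −0.11 (17 tested, mean −0.02, adjusted p = 0.812, camera direction up; Mt1 −1.83, SE 0.92). Circadian clock genes stood at 0.05 (0.961; Nr1d2 0.64, Cry2 −0.51), endoplasmic reticulum stress genes at 0.14 (0.921; Asns 0.56, Atf4 −0.47) and heat shock proteins at 0.04 (mean −0.03; 0.921; Hspb8 −0.54, Hsp90ab1 −0.35). Antioxidant genes stood at 0.12 (0.610; Cat 0.93, Keap1 −0.55), cell proliferation genes at 0.24 (0.312; Mki67 1.11, Top2a 0.57) and polyamine and amino acid metabolism at −0.08 (0.812; Psat1 1.05). Without RA replicate 4, Tap2 stood at 0.01, Cry2 at −0.22, Atf4 at −0.26, Hspb8 at −0.21, Hsp90ab1 at −0.08, Keap1 at −0.23 and Socs3 at −0.09. Socs3 stood at −0.14 and Cry2 at −0.33 without RA+Dipy replicate 1, Nr1d2 at 0.23 without both, Asns at 0.28 without RA+Dipy replicate 4 and Top2a at 0.38 and 0.37 without RA replicates 1 and 3. With 1 library left out, medians turned negative without RA+Dipy replicate 1 for endoplasmic reticulum stress (−0.06), heat shock (−0.06) and NF-kB targets (−0.00158), and without RA+Dipy replicate 2 or 4 for the clock (−0.04 each). The heat shock median was also negative without RA replicate 2 (−0.04), RA replicate 4 (−0.06) or RA+Dipy replicate 3 (−0.04). The antioxidant median was 0.00525 without RA+Dipy replicate 1 and −0.09 without both libraries that stood apart. The proliferation median was 0.16 without RA replicate 3 and −0.09 at a mean of at least 1 CPM. The glucocorticoid median ran from −0.21 (without RA replicate 1) to 0.11 (without RA replicate 4 or 2), with 0.04 without RA replicate 3 and −0.00298 without RA+Dipy replicate 3, and the polyamine median 0.06 without RA replicate 2. No gene of these 9 lists passed, adjusted over the list alone or over all genes.

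Markers of the remaining cell types did not pass in the fit described so far. With GC and length offsets the fibroblast (adjusted p = 0.00209), tendon (0.00236) and neutrophil (0.0396) lists passed as higher by camera with the preset correlation. With an estimated correlation and no offsets, their adjusted p was 0.764, 0.845 and 0.845. Fibroblast and fibro-adipogenic progenitor markers had a median of 0.15 (12 tested, adjusted p = 0.0641; Col15a1 0.57), and 3 of them, Col15a1, Dcn and Lum, are also on the matrix list. Tendon markers had a median of 0.47 (9 tested, 0.0741; Kera 1.24, Cilp 0.97). Endothelial markers stood at 0.02 (12 tested, mean −0.07, 0.999; Egfl7 −1.19, Tek 0.43) and mural cell markers at −0.01 (11 tested, 0.784; Acta2 −0.67, Lmod1 −0.53). Egfl7 stood at −0.28, Tek at 0.27, Acta2 at −0.24, Lmod1 at −0.20, Sfn at −0.25 and S100a9 at 1.46 without RA replicate 4. Cilp stood at 0.63 without RA+Dipy replicate 3, Csf3r at 0.37 without RA+Dipy replicate 4 and Krtdap at 0.49 without RA replicate 1 or RA+Dipy replicate 1. Cd2 ran from −0.03 to 0.52 with 1 library left out. The score averaged over both vascular lists differed by −0.06 (SE 0.08) between the groups. Neutrophil markers had 3 tested members and a median of 0.67 (0.213; Csf3r 0.67, S100a9 0.86), and T cell markers 3 and −0.03 (0.784; Cd3e −0.51, Cd2 0.18). Keratinocyte markers had 3 and 0.59 (0.921; Sfn −0.83, Krtdap 0.78) and erythroid markers 5 and 0.54 (mean −0.32, 0.961; Hba-a2 −1.88, SE 1.00, and Hba-a1 −1.66, SE 0.92, a near-identical pair that stood at 0.48 and 0.38 without RA replicate 4). Without RA replicate 4 the fibroblast (0.00257) and neutrophil (8.07e-05) lists passed. Without RA+Dipy replicate 2 the fibroblast (0.0472) and tendon (0.0127) lists did, without RA+Dipy replicate 4 the fibroblast (0.0340) and tendon (0.0249) lists, and without RA replicate 3 the tendon list (0.00103). Medians moved too. Without RA+Dipy replicate 1 they were −0.27 for keratinocyte, −0.24 for erythroid and 0.14 for tendon markers, and without RA+Dipy replicate 2 0.72 for tendon markers. Without RA replicate 4 they were 0.29 for fibroblast, 1.23 for neutrophil, −0.26 for T cell, 0.12 for mural and 0.07 for endothelial markers. At the other end, the T cell median was 0.09 without RA replicate 1, the mural median −0.09 without RA replicate 2 and −0.07 without RA replicate 1, the endothelial median −0.08 without RA+Dipy replicate 2 and the neutrophil median 0.37 without RA+Dipy replicate 4. The adjusted p ranged from 0.00209 to 0.437 (fibroblast), 8.07e-05 to 0.690 (neutrophil) and 0.00103 to 0.536 (tendon). No gene of these 8 lists passed, adjusted over the list alone or over all genes.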

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

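Tests chosen only after the result was seen were those of depth and of the GC and length trend for the 2 libraries that stood apart, and those of the effect of these 2 libraries on the matrix, macrophage, junction, calcium and Schwann cell lists.

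Each value named here comes from 1 library that lay far from the other 3 of its group (a gap of more than 0.829 of the group's range), and chance alone would single out about 1 group in 20. Of 304 group values examined 31 did so, where chance gives about 15.2, with 8 in RA replicate 4 and 11 in RA+Dipy replicate 1. Among list scores (mean log2 CPM), RA+Dipy replicate 4 stood at 5.24 for slow-fibre genes (others 6.42 to 6.63), at 6.25 for adipocyte markers (3.64 to 4.08) and at 2.78 for the interferon response (2.57 to 2.59). RA replicate 4 stood at 7.27 for the tricarboxylic acid cycle (8.29 to 8.48), RA replicate 2 at 2.64 for the adenosine list (2.43 to 2.45), RA+Dipy replicate 2 at 2.78 for macrophage markers (3.58 to 3.63) and RA+Dipy replicate 1 at −0.57 for T cell markers (0.49 to 0.57).

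Among genes (CPM), RA replicate 4 was far from its group for Postn (4.82, others 11.2 to 13.1), Psmd2 (1130, others 284 to 305), mt-Nd4 (15382, others 5910 to 6852), Mt1 (259, others 13.4 to 21.1), Col15a1 (22.2, others 33.4 to 36.2), Cilp (18.8, others 63.0 to 71.2) and Igf1 (83.1, others 27.2 to 31.6). RA+Dipy replicate 1 was far for Dok7 (9.63, others 13.0 to 13.5), Atg12 (42.0, others 24.6 to 25.9), Actn3 (4143, others 8840 to 9152), Pygm (3605, others 8053 to 9091), Igf1r (21.0, others 11.5 to 12.2), Cry2 (20.7, others 36.4 to 39.4), Cd2 (0, others 0.517 to 0.560), Igf1 (72.3, others 28.0 to 32.6), Pax7 (0.990, others 1.92 to 2.07) and Ppargc1a (30.2, others 21.7 to 22.3). RA+Dipy replicate 4 was far for Adipoq (101, others 19.9 to 22.9), Mbp (33.5, others 55.4 to 59.0) and Cdkn1a (18.3, others 19.8 to 19.9). RA+Dipy replicate 2 was far for Doc2g (0.628, others 0.231 to 0.264) and Fbxo32 (319, others 145 to 153), RA replicate 1 for Pck1 (4.75, others 7.69 to 8.30) and RA replicate 3 for Megf10 (0.469, others 0.768 to 0.845).

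RA replicate 4 and RA+Dipy replicate 1 stood apart from the other 6 libraries. Lower depth was argued against: with the other 6 libraries thinned to the smallest total, the spread of either library was still at least 2.68 times the largest of theirs. A trend on GC content and transcript length was argued against as the whole cause, since the ratio was 2.83 after such trends were removed. RNA from other cell types would shift genes active in muscle fibres alone by a common factor. The SD of the deviations of fast-sarcomere, glycolysis and tricarboxylic acid cycle genes in either library was at least 2.94 times the largest among the other 6. Glycolysis and tricarboxylic acid cycle genes are active in other cells too, so such RNA could itself widen this spread. The test therefore cannot decide, and RNA from other cell types stays open. Degraded RNA, a library batch or a sample of another origin may still account for the 2 libraries, which come from different groups, and none of these was tested.

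The matrix and macrophage lists rose with dipyridamole by camera with the preset correlation, and neither passed with an estimated one (adjusted p = 0.667 for each). The 2 libraries that stood apart were argued against as the cause, since the medians without them were at least 1.03 times those with all 8, and so was the GC and length trend as the whole cause, since at least 0.881 of each median was left with offsets (0.985 for the matrix list). A lower share of muscle-fibre RNA would raise vascular markers alike, yet the macrophage score rose by 0.703 (SE 0.306) log2 units more than the vascular scores. No such comparison was made for the matrix list. With 4 libraries per group the margin is imprecise, so a lower share is not excluded. Chance stays open: the exact permutation p of the score was 0.0286 for the matrix list and 0.0571 for the macrophage list, each 0.781 after adjustment. Of the 35 splits of the 8 libraries, 9 gave at least as many lists (real 10, highest other 14). That count covers lists of any kind, so it cannot decide for these 2. An effect of the drug and a difference in dissection, which may change the tissue around the fibres, also stay open, untested.

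Lists of nerve and muscle excitation fell with dipyridamole by camera with the preset correlation, and none passed with an estimated one (adjusted p = 0.667 for Schwann cell markers, 0.764 for the junction list and 0.764 for the calcium list). For the junction and calcium-handling lists the values fit the 2 libraries that stood apart as a candidate explanation: without them at most 0.462 of the median was left (0.128 for the junction list) and neither list passed. The Schwann cell list kept 0.910 of its median without them and still passed with the preset correlation (adjusted p = 0.00123; 0.699 with an estimated one), which argues against the 2 libraries as its whole cause. The falls of its named genes were smaller without them: Mbp went from −0.98 to −0.51, Prx from −0.88 to −0.50 and Sox10 from −1.04 to −0.71. RA replicate 4 also had the highest score for the list (4.07, other RA libraries 2.95 to 3.61), so a part of the fall may come from that library. The amount of nerve in each piece of muscle and an effect of the drug on nerve or Schwann cells stay open for that list, untested. So does chance, with an exact permutation p of the score of 0.114 (0.837 after adjustment). The splits named above count lists of any kind and cannot decide for this list.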

How the results depend on the processing

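The fit without the 2 libraries that stood apart, the GC and length offsets and the exact permutation of scores were chosen after seeing the data; the other alternatives were planned. Gene counts stayed at 0 higher and 0 lower in 19 of 20 alternatives (smallest adjusted p 0.418 to 0.998) and were 111 and 22 in limma-voom with library weights, which gave the 2 libraries the lowest weights; the cause was not tested further. Lists passing went from 10 to 13 with GC and length offsets, to 6 with DESeq2 size factors, to 0 with the estimated correlation and to 0 by fry, with 6 to 12 when 1 library was left out. The replicate numbers did not pair the samples (correlations between same-numbered libraries −0.196, 0.112, 0.148 and −0.266). With the replicate block 0 genes passed in either direction, 165 had an unadjusted p under 0.05 and 12 lists passed, fatty acid oxidation (0.0173) and tendon markers (0.0162) among them. For a gene, a change of sign was counted as a reversal when either value was called or the value moved by more than 1 SE. For a list, it was a change of camera's direction where either value was called. By these rules 14 genes and 2 lists reversed, for which the cause was not tested. The median of the ribosomal list also changed sign, to 0.12, 0.00148, 0.02 and 0.07 without RA replicate 4 or RA+Dipy replicate 2, 3 or 4, where its call was lost and camera's direction stayed down. With library weights the log2 fold change was 0.0253 for mt-Nd1, 0.0649 for mt-Nd4 and 0.38 for Mstn. Without the 2 libraries it was 0.11 for mt-Nd1, 0.20 for mt-Nd4, 0.63 for Adora1 and −0.38 for Socs3. With GC and length offsets it was 0.00413 for Myod1 and −0.18 for Ppargc1a. With 1 library left out, values ran from −0.59 to 0.12 for mt-Nd1, −0.57 to 0.0470 for mt-Nd4, −0.65 to 0.0458 for Igf1r, −0.90 to 0.0126 for Tap2, −2.22 to 0.37 for Mt1, −2.43 to 0.48 for Hba-a2, −2.18 to 0.38 for Hba-a1, −0.30 to 0.35 for Mstn, −0.47 to 0.50 for Igf1, −1.54 to 0.40 for Adora1 and −0.27 to 0.24 for Pde5a. The upper end came without RA replicate 4 for each of these but Mstn, for which it came without RA replicate 2. The antigen presentation list had an adjusted p of 0.000566 without the 2 libraries and of 0.00103 to 0.997 with 1 left out, and adipocyte markers of 1.70e-05 to 0.647. The median fold change of all genes moved from 0.00972 to 0.0832 across scalings. The cytokines Il6, Tnf and Il1b had at most 9 counts in a library and were not tested.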

Other observations

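The tests without the 2 libraries that stood apart and the count of splits for genes past the adjusted threshold were chosen only after the results were seen.

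Camera with the preset correlation called further lists without RA replicate 4 and RA+Dipy replicate 1. Nuclear oxidative phosphorylation genes were called lower in RA+Dipy (76 genes, median log2 fold change −0.37, adjusted p = 6.49e-12). So were proteasome subunits (39 genes, median −0.23, adjusted p = 4.04e-08). Antigen presentation genes (14 genes, median 0.31, adjusted p = 0.000566) and fibroblast markers (12 genes, median 0.15, adjusted p = 0.00418) were called higher. With an estimated correlation none of these lists passed (adjusted p = 0.725, 0.699, 0.647 and 0.699, in that order). None of them passed with all 8 libraries in the fit of the report. For oxidative phosphorylation the list score of RA replicate 2 (7.75) lay below that of RA+Dipy replicate 2 (8.06), so the groups overlapped. The same held for proteasome subunits (6.52 and 6.54). With GC and length offsets and all 8 libraries, the fibroblast list passed (adjusted p = 0.00209, the lowest of a range to 0.437). The other lists did not: the median was −0.03 for oxidative phosphorylation (adjusted p = 0.813), −0.07 for proteasome subunits (0.482) and 0.15 for antigen presentation (0.112). Without the 2 libraries and with an estimated correlation, 0 of all lists passed camera, and the smallest adjusted p was 0.398, for the interferon response (unadjusted p = 0.00996).

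With library weights, limma-voom called 133 of 12755 genes. They included 9 of 34 extracellular matrix genes, 5 of 30 interferon-response genes and 3 of 14 macrophage markers, each of them higher. Named genes among the 133 included Ctss, Ifit2, Postn, Gbp3, Parp14, Lum, Col3a1, Mpeg1, Ucp3 and Mki67. Of the 133, 131 had the same sign in edgeR with all 8 libraries, where 69 had an unadjusted p under 0.05. Both fits used the same counts, so this agreement of sign is no separate support.

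Chance could not be excluded for any count over the 35 splits of the 8 libraries into 4 and 4, the real one included. The real count of genes past the adjusted threshold was 0 in edgeR (488 at an unadjusted p under 0.05; DESeq2 0), so that 35 of 35 splits gave as many, which says nothing, and the highest other split gave 1. At an unadjusted p under 0.05, 14 of 35 splits gave at least the real 488 genes and the highest other gave 2919. For lists passing camera it was 9 of 35 (real 10, highest other 14), and for genes called with library weights 7 of 35 (real 133, highest other 2119). Splits that call several times the real count point to a structure of the samples. Of the 13 other splits with at least 488 genes, 11 put RA replicate 4 and RA+Dipy replicate 1 in the same group of 4, the one with 2919 among them. Of the 20 splits that keep these 2 libraries apart, as the real one does, 3 gave at least 488 genes, the real one included (highest other 1104), a comparison made after the counts were seen that does not exclude chance either. What else the structure holds was not tested. Among the 6 libraries that lay close together, RA replicates 1 and 3 with RA+Dipy replicate 2 against the rest gave 514 genes past the adjusted threshold, where the real split gave 0 (1461 at an unadjusted p under 0.05). For lists without the 2 libraries, 6 of 10 splits gave at least the real 12 and the highest other gave 14; 10 splits are too few for a share under 0.05.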
